A study of Gallus gallus with 12 samples.

How the data were processed

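Total RNA was extracted from magnum and uterus of Lohmann layers with the RNAsimple Total RNA Kit, and libraries were made with a Smarter mRNA-seq kit, per the labels' protocols. The 12 libraries fall into 4 groups of 3, magnum and uterus at 120 and at 300 days of age, as the sample titles give them. Nothing in the labels says that the 3 libraries of a group came from separate hens, so the p-values measure only the spread between these samples, which may be partly technical. No 2 libraries held identical values. FastQC 0.11.6, Trimmomatic 0.32, TopHat2 2.0.8, GATK 3.8 and Cufflinks 2.0.2 were used, per the submitters' processing notes, which give no role or order for them. The genome build, the annotation and the way reads were counted are not given in the sources used here, so reads shared between near-identical genes or between overlapping genes could not be judged.

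The deposited gene table holds whole numbers for 19820 genes, and these were treated as scores, that is scaled read counts and not raw counts. Raw counts of different libraries would differ in size factor, but the median-of-ratios size factors of the 12 columns all lay between 0.974 and 1.013 while the column totals ran from 14499548 to 77432154. In 4 magnum libraries low values also skipped whole numbers at regular intervals. The value of 1 read, as the step whose truncated multiples held the largest excess of values up to 100, was 1.167 in replicate 1 at 120 days and 2.267, 2.371 and 1.951 in replicates 1 to 3 at 300 days. Those steps held 99.1%, 96.0%, 96.5% and 96.95% of the values, where their share of all whole numbers was 86.0%, 44.0%, 42.0% and 51.0%. In the other 8 libraries no number was skipped and 1 read is worth less than 1, so whole reads could not be recovered, the depth is unknown, and a listed 0 does not exclude a read. The second deposited table holds FPKM values for the same genes. The divisor implied by the gene lengths was about 21100000 to 24600000 in all 12 libraries, so the deposited FPKM values stand on nearly the same common scale and not on each library's own total. Both deposited tables therefore show levels relative to a typical gene, and where a few genes take most of a library this differs strongly from a share of the library.

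The identifiers of the tables consist of 18241 numbered genes and 1579 loci that carry a new-gene label. None of them (0 of 19820) matched a gene ID, locus tag, symbol, synonym, Ensembl ID or accession in the reference table of chicken genes (assembly GRCg7b), so no symbols were assigned. The 25 gene lists fixed before the data were examined, with 1000 entries, had 0 entries matched and were not tested. The rule for named genes fixed at the same time required a symbol and named no gene. In its place, after values were seen, the most abundant rise and fall with a log2 change of at least 1 in each age comparison were taken, and the gene with the most negative difference between uterus and magnum at 120 days. A gene had to pass the threshold, reach a group mean of 200 and have non-overlapping libraries. The same gene was the most abundant fall in both segments, which leaves 4 identifiers. No fold is given against a group in which a gene is listed at 0 in all libraries.

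The test planned before the data were examined was a count model, which is made for raw counts and not for scaled and truncated values. The test used instead was limma's moderated test with a mean-dependent prior (limma 3.58.1 in R 4.3.3) on log2(scaled count + 1), two-sided. It took genes with a value of at least 10 in at least 3 libraries (14883 genes, of which 1114 were new-gene loci). All 12 libraries entered 1 fit with a coefficient per group, giving 8 residual degrees of freedom, and a Benjamini-Hochberg adjusted p below 0.05 was the threshold. The comparisons were 300 against 120 days in each segment, uterus against magnum at each age, and the interaction, the uterus age change minus that of the magnum. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Principal components and correlations used the same log values (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

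The test was run on simulated data with 200 genes changed by known folds. Each gene took its mean over all 12 libraries and its spread from the fit of all 4 groups, the same in every group. The wider spread of the 120-day groups was therefore left out. For the magnum age comparison, folds were applied to the magnum at 300 days, among 14452 genes. The test then recovered 25.8% of 66 genes changed 2-fold, 58.0% of 69 changed 4-fold and 87.7% of 65 changed 8-fold. Over the 4 comparisons of 2 groups, 69.0% to 87.7% of the 8-fold changes were recovered. Unchanged genes made up 7.32% of the calls in the magnum age comparison, and 3.54% to 8.53% over the 4 comparisons. In this simulation 2-fold changes were mostly missed with 3 libraries per group. The Benjamini-Hochberg cutoff is looser where far more than 200 genes change, so these shares do not carry over to comparisons with many calls.

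Replicate numbers are shared between groups, and whether they pair libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. Between magnum and uterus at 120 days the 3 correlations were 0.361, 0.591 and 0.390, so the numbers were taken to pair the segments at that age. At 300 days they were weaker, at 0.198, 0.216 and 0.0838, while libraries with different numbers gave -0.18 to -0.0164. Whether the numbers pair the segments at 300 days was therefore left undecided. Between ages all same-numbered correlations were below 0, so there the libraries share only a number. Alternatives were other scalings (median of ratios, upper quartile, library total), leaving out the 20 most abundant genes, other filters, the FPKM values with pseudocounts of 1 and 0.1, the replicate number as a block, fits of the 2 groups compared alone, a log2 change of at least 1, and leaving out each library in turn. A pseudocount of 10, and leaving out replicate 1 of both segments at 120 days, were added after the data were seen.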

Results

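Messenger RNA was sequenced from 2 segments of the oviduct of Lohmann layers, a commercial strain of egg-laying chicken (Gallus gallus). The magnum is the segment that secretes egg white, and the uterus, or shell gland, is the segment where the eggshell is formed. Each segment was sampled at 120 and at 300 days of age, with 3 libraries per group and 12 libraries in all. The series title speaks of hens before and during lay, and its stated aim is to learn how the segments differ in function and in the defense of the oviduct and the egg. The deposited gene table lists 19820 genes as read counts that had already been scaled to a common level, called scaled counts here. The columns summed to 14499548 to 25071610 scaled counts in the magnum at 120 days and to 44995822 to 77432154 at 300 days. In the uterus they summed to 14543795 to 15468376 at 120 days and to 16376839 to 17274374 at 300 days. These totals are not sequencing depth. In 4 magnum libraries the values fell on regular steps from which the number of reads assigned to genes could be estimated, as about 21500000 for replicate 1 at 120 days and 27500000, 32700000 and 23100000 for replicates 1 to 3 at 300 days. The depth of the other 8 libraries is unknown.

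The gene table names its genes by numbered identifiers that it does not pair with gene symbols, and 0 of the 19820 identifiers matched the reference table of chicken gene names used here. No gene name, position or pathway is therefore given, and none of the 25 gene lists fixed for these tissues could be tested. Genes are described below as groups, and 4 identifiers, chosen after their values were seen, stand as examples. Of these, gene8291 rose with age in the uterus and, at a low level, in the magnum, and gene11472 fell in both segments. In the magnum gene4368 rose with age, as did gene17377, which was lower in the uterus than in the magnum.

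The magnum at 300 days was dominated by a small number of very abundant genes. Its 10 most abundant genes held 68.3% ± 6.89 of all scaled counts (SD, n = 3), against 16.5% ± 19.0 in the magnum at 120 days, 6.52% ± 1.60 in the uterus at 120 days and 9.96% ± 0.410 in the uterus at 300 days (SD, n = 3 each). The most abundant gene alone took 49.3%, 53.4% and 36.1% of the 3 magnum libraries at 300 days. The wide spread at 120 days came from replicate 1 of the magnum, in which the 10 most abundant genes held 38.5%, against 5.94% and 5.05% in replicates 2 and 3. The first principal component, with 40.9% of the variance, set the magnum at 300 days apart from the other groups, and the second, with 27.6%, separated the uterus at 300 days from the 120-day libraries. Across genes, which are not independent replicates, libraries of one group correlated at 0.900 to 0.966 in the magnum and 0.889 to 0.939 in the uterus at 120 days, and at 0.9445 to 0.952 and 0.964 to 0.975 at 300 days.

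**Figure D1:**
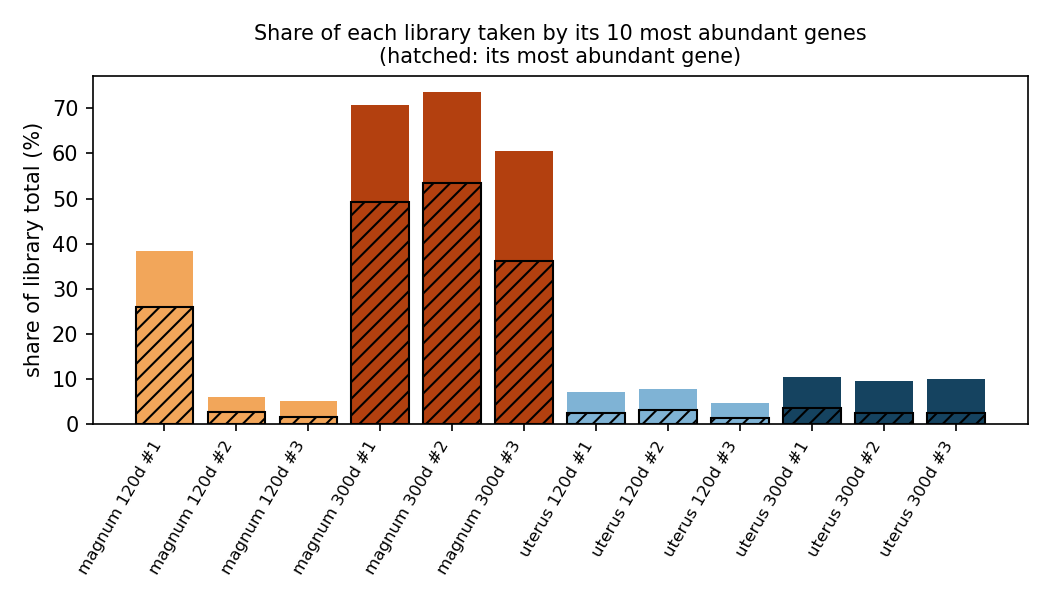
Share of each library's total scaled counts, in percent, held by its 10 most abundant genes (bars) and by its most abundant gene alone (hatched part), for the 12 libraries. The 3 magnum libraries at 300 days lie between 60.5% and 73.6%, replicate 1 of the magnum at 120 days at 38.5%, and the others between 4.715% and 10.35%.

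**Figure D2:**
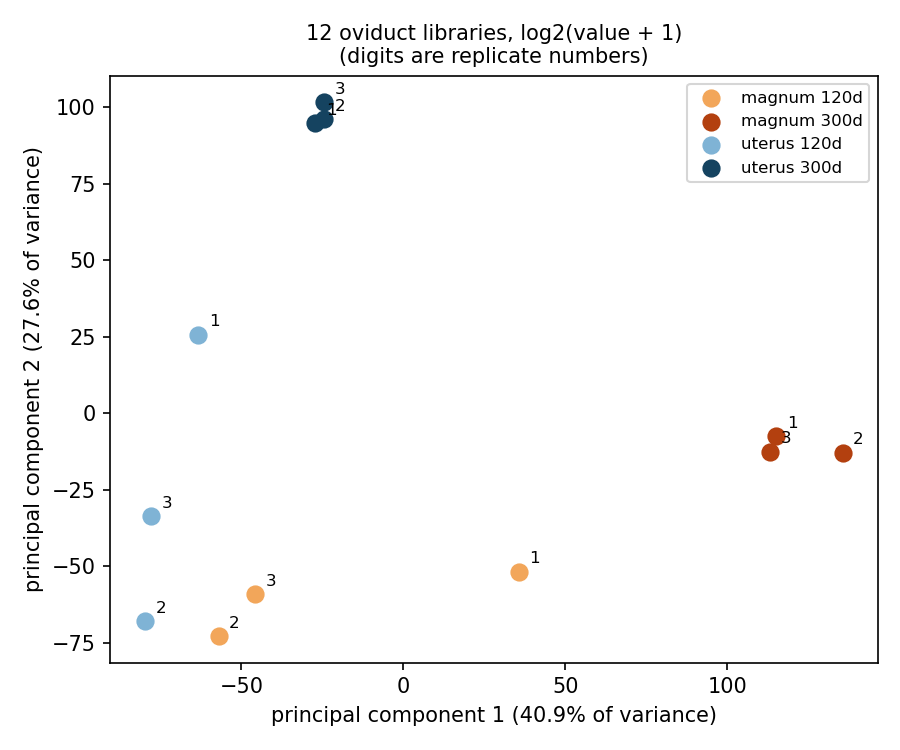
Principal components 1 and 2 of the 12 libraries, from log2(scaled count + 1) of the 14883 genes tested, with no unit on either axis; colours mark the 4 groups and digits the replicate numbers. The 300-day libraries of each segment lie together, and replicate 1 of each segment at 120 days lies between its group and the 300-day libraries of that segment.

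In the magnum, 1794 genes were higher and 2023 lower at 300 days than at 120 days, together 25.7% of the 14883 genes tested. Of these, 1013 rose and 1725 fell at least 2-fold, and 92 rose and 175 fell at least 16-fold. Among the genes that rose was gene4368, the most abundant of them, from 2189811 ± 3742374 to 29423225 ± 12606104 scaled counts (SD, n = 3 each), a log2 change of 7.89 ± 1.85 (SE, adjusted p = 0.0106). Its 3 values at 120 days were 6511037, 4406 and 53990, so that the spread at that age came mostly from replicate 1. The log2 change was 10.80 without that library and 5.53 without replicate 2. Replicate 2 held the gene at 0.015% of its 300-day magnum mean, within the 0.00791% to 0.0151% of the uterus libraries. A floor at that level may limit how far this fold can be read. The rise of gene17377 was from 31015 ± 51715 to 377197 ± 44731 scaled counts, a log2 change of 6.25 ± 1.25 (SE, adjusted p = 0.00481), and its values at 120 days were again highest in replicate 1. It was 8.35 without that library, 5.13 without replicate 2 and 5.265 without replicate 3. Among the genes that fell, gene11472 was the most abundant and dropped from 52361 ± 15454 to 3407 ± 627 scaled counts, a log2 change of -3.91 ± 0.29 (SE, adjusted p = 3.8e-05). The 26 genes with a mean of at least 50000 at 300 days included 21 that rose and 0 that fell, although their selection by the 300-day level favours a rise. They held 73.1%, 76.55% and 64.1% of the 300-day magnum libraries, 40.5% of replicate 1 at 120 days, and 4.93% and 4.50% of replicates 2 and 3. Genes whose 3 libraries of one age all lay above the 3 of the other made up 39.1% of those tested, where chance gives 10%.

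The test was limma's moderated test on log2(scaled count + 1), with Benjamini-Hochberg adjustment. The division into rises and falls depended on the scaling: 47.0% of the calls were rises in the deposited scaling, 36.9% after upper quartile rescaling, 61.2% with the deposited FPKM values, and 1.05% (131 rises, 12378 falls) when each library was divided by its own total. Fits without replicate 2 or 3 at 120 days gave 953 and 796 rises with 1168 and 996 falls, and the fit without replicate 2 at 300 days gave 1111 rises. A fit of the 2 magnum groups alone gave 1025 rises and an adjusted p of 0.57 for gene4368, where its alternatives ranged from 1.4e-05 to 0.57. For gene17377 the fit of the 2 magnum groups gave an adjusted p of 0.0445. The main fit takes the SE of both genes from all 4 groups, which dilutes their wide spread in the magnum at 120 days.

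In the uterus, 973 genes were higher and 1073 lower at 300 days than at 120 days, 13.75% of the genes tested. At least 2-fold changes were seen in 596 of the rises and 946 of the falls, and at least 16-fold changes in 61 and 108. The most abundant gene that rose, gene8291, went from 77.0 ± 43.6 to 257501 ± 52994 scaled counts (SD, n = 3 each), a log2 change of 11.83 ± 0.36 (SE, adjusted p = 5.74e-09). It was listed at 0 in the 3 magnum libraries at 120 days and at 172, 227 and 201 in those at 300 days, a rise that also passed (adjusted p = 1.47e-06) and for which no fold is given. These magnum values are very low beside the uterus level at 300 days. Carry-over of uterus reads or RNA into the magnum libraries was not tested and could give such a rise. The most abundant gene that fell was again gene11472, from 97446 ± 24411 to 4775 ± 933 scaled counts, a log2 change of -4.34 ± 0.29 (SE, adjusted p = 2.79e-05). Of the 8 genes with a mean of at least 50000 in the uterus at 300 days, 3 rose and 0 fell, again a group selected by its 300-day level. They held 9.46%, 8.95% and 9.36% of the 300-day uterus libraries, and 2 of them were also among the 26 such genes of the magnum. Neither gene4368, with a log2 change of 0.33 ± 1.85 (SE, adjusted p = 0.926), nor gene17377, with 0.52 ± 1.25 (adjusted p = 0.818), passed in the uterus. Their SE comes from the spread of all 4 groups, which the magnum at 120 days widened. The uterus values of gene4368 lay closer, at 2326 to 3561 at 120 days and 3558 to 4435 at 300 days. Non-overlapping libraries were found for 39.3% of genes, against 10% by chance.

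The counts came from the same limma fit of all 12 libraries. They moved when single uterus libraries were left out: without replicate 2 or 3 at 120 days 390 and 467 genes rose and 532 and 559 fell, without replicate 1, 2 or 3 at 300 days 424, 426 and 454 rose and 558, 551 and 577 fell. Without replicate 1 of both segments at 120 days, an alternative added after the data were seen, 1501 rose and 1624 fell; dividing by library totals gave 331 rises and changed the share of rises from 47.6% to 30.4%.

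Many genes changed with age in the same direction in both segments. Both rises were found for 354 genes, where independent lists of the same sizes would share 117.3, and both falls for 672, against 145.8. Opposite changes were found for 52 genes, against 261.6, of which 43 fell in the magnum and rose in the uterus and 9 did the reverse. The log2 changes of the segments correlated at 0.517 across the 14883 genes (Pearson), which are not independent replicates. The 2 age comparisons share no library, but the labels do not say whether a magnum and a uterus library came from the same hen, and same-numbered libraries of the segments deviated together at 120 days. Independent lists leave out such shared deviations, and also the spread of each gene, which both comparisons took from the same fit. The excess over them is therefore not read as a shared age change. The covariance of the log2 changes over genes was 0.769, and the deviations shared by same-numbered libraries gave an estimated 0.0998, of which 0.0809 came from 120 days. How much of the overlap of calls they gave was not separated. The 1026 shared changes in the same direction became 1723 without replicate 1 of both segments at 120 days. Leaving out replicate 2 or 3 of the magnum at 120 days gave 682 and 596, replicate 2 or 3 of the uterus at 120 days 568 and 554, and replicate 1, 2 or 3 of the uterus at 300 days 549, 532 and 563.

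**Figure D3:**
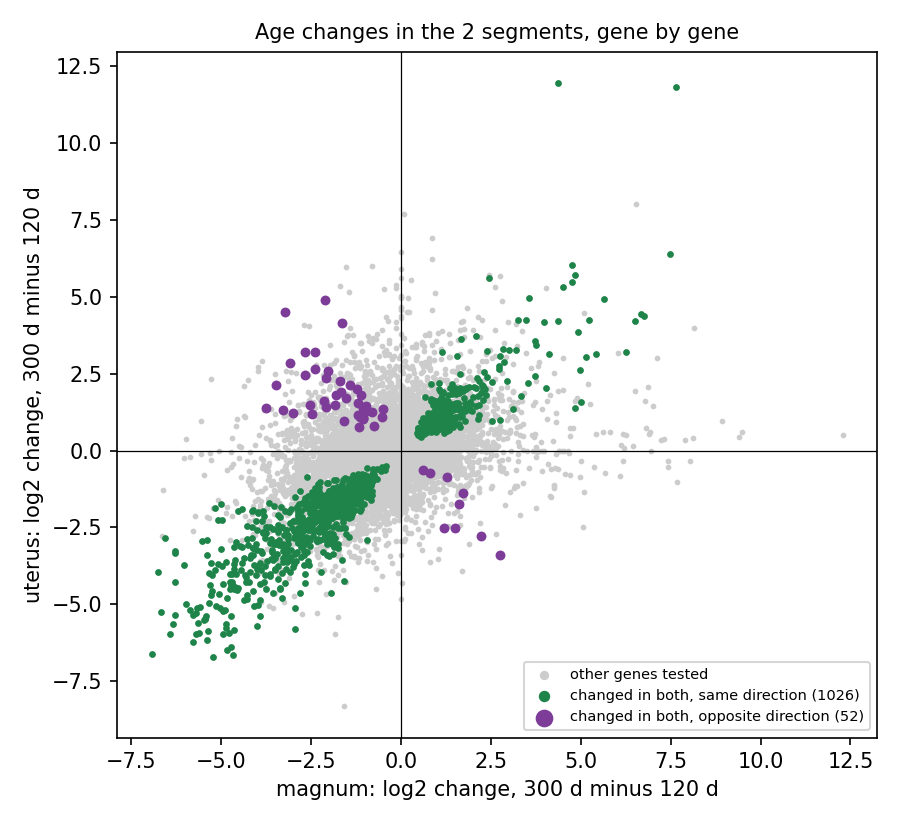
Log2 change from 120 to 300 days in the magnum (x axis) against that in the uterus (y axis) for the 14883 genes tested, from log2(scaled count + 1). Green points mark the 1026 genes that changed in the same direction in both segments and purple points the 52 that changed in opposite directions.

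At 120 days few genes passed the test between the segments: 36 genes were higher and 56 lower in the uterus than in the magnum, 0.618% of the genes tested. The largest difference toward the magnum was that of gene17377, at 31015 ± 51715 scaled counts in the magnum and 35.7 ± 8.62 in the uterus (SD, n = 3 each), a log2 change of -7.10 ± 1.25 (SE, adjusted p = 0.0269). Its 3 magnum values were 90730, 1049 and 1266, all above the uterus values of 45, 34 and 28. The log2 change was -5.00 without magnum replicate 1, -8.22 without replicate 2 and -8.08 without replicate 3. The uterus values also lay near the level of 29.8 to 45.7 that the gene would have there at the fraction of its 300-day magnum mean at which gene4368 stood in the same libraries, so the size of this fold is limited by that floor. The magnum value of gene4368 was also above the uterus in all libraries of this age, but its log2 change of -5.24 ± 1.85 did not pass (adjusted p = 0.33). Magnum replicate 2 held it at 0.015% of its 300-day magnum mean, within the 0.00791% to 0.0151% of the uterus libraries of both ages. Listed at 0 in the 3 magnum libraries, gene8291 stood at 124, 69 and 38 in the uterus and passed (adjusted p = 1.8e-05). Genes with non-overlapping libraries made up 13.3%, against the 10% that chance gives for independent libraries. That 10% leaves out the pairing of same-numbered libraries at this age.

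This comparison rested on few calls and on the spread shared across all groups, since a limma fit of the 6 libraries alone gave 2 higher and 1 lower. With same-numbered libraries of an age as blocks, 35 were higher and 61 lower, and 61 of the 92 genes kept call and direction. With the replicate number as a block over both ages, 20 were higher and 38 lower, with 55 of the 92 kept. The call of gene17377 was lost in 9 of the 12 fits that left out a library (adjusted p 0.0503 to 0.0925), with the FPKM values at a pseudocount of 1 (0.0614, or 0.106 with no filter) but not at 0.1 (0.0414), and with the 6 libraries alone (0.338), where all of its alternatives ranged from 5.12e-06 to 0.338. That of gene8291 was lost with the 6 libraries alone (adjusted p = 0.0598) and with the FPKM values at a pseudocount of 1 (0.0761, or 0.113 with no filter) but not at 0.1 (0.000679), where its alternatives ranged from 4.02e-06 to 0.113. Counts of higher and lower genes were 17 and 17 without magnum replicate 3, 15 and 26 without uterus replicate 1, 21 and 35 without uterus replicate 3, and 14 and 29 without replicate 1 of both segments. Without uterus replicate 2, 65 were higher, without uterus replicate 2 at 300 days 22 were higher, and without uterus replicate 1 at 300 days 36 were lower. With the FPKM values 19 were higher and 27 lower.

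At 300 days the segments differed widely, with 1916 genes higher and 1677 lower in the uterus, 24.1% of those tested. At least 16-fold differences were found for 304 genes toward the uterus and 150 toward the magnum. For gene8291 the uterus held 257501 ± 52994 scaled counts against 200 ± 27.5 in the magnum (SD, n = 3 each), a log2 change of 10.31 ± 0.36 (SE, adjusted p = 3.93e-08). For gene4368 the uterus held 3874 ± 487 against 29423225 ± 12606104, a log2 change of -12.80 ± 1.85 (SE, adjusted p = 0.000611). For gene17377 the values were 51.3 ± 10.97 in the uterus and 377197 ± 44731 in the magnum, a log2 change of -12.83 ± 1.25 (SE, adjusted p = 5.51e-05). The uterus libraries held gene4368 at 0.00791% to 0.0151% of its 300-day magnum mean, and 0 of 150 values of the 25 next most abundant magnum genes lay below 0.5 times that fraction, a floor that limits how far such folds can be read. Non-overlapping libraries were found for 44.1% of genes, against 10% by chance.

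The share of these calls that were higher in the uterus was 53.3% in the deposited scaling, 36.7% with the FPKM values (1509 higher, 2599 lower) and 98.05% after division by library totals (12351 higher, 246 lower). The segment differences of the 2 ages overlapped for 28 genes higher in the uterus and 53 lower, where independent lists would share 4.635 and 6.31, and 1 gene went in opposite directions. Both comparisons took the spread of each gene from the same fit, which independent lists leave out, so part of the excess may come from that. The overlap of 81 became 31 without magnum replicate 3 at 120 days, 36 and 50 without uterus replicate 1 or 3 at 120 days, 49 without uterus replicate 1 or 2 at 300 days, and 39 without replicate 1 of both segments at 120 days. It was 2 when only the 2 groups compared were fitted, 51 with the replicate number as a block over all libraries, and 37 with the FPKM values at a pseudocount of 1 (41 with no filter) or 52 at 0.1.

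**Figure D4:**
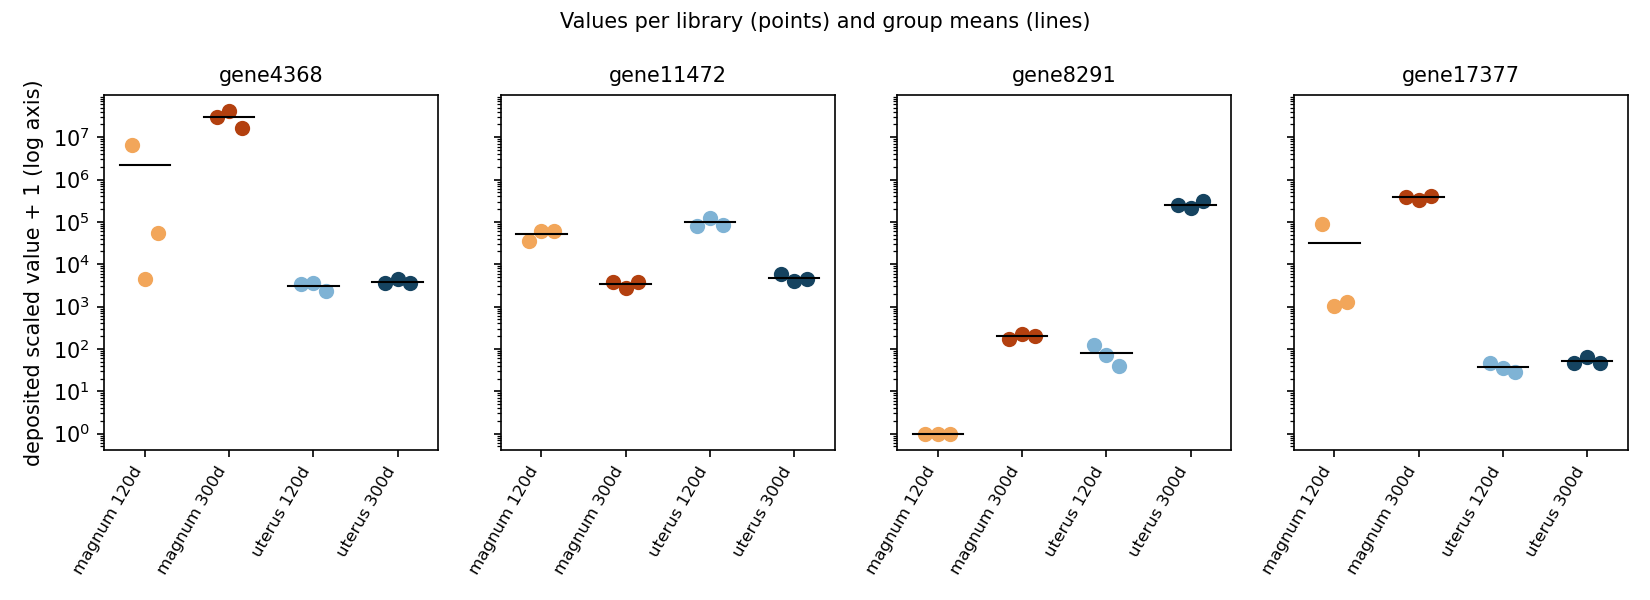
Scaled counts plus 1 of the 4 example genes on a log axis, 1 point per library and a line at the mean of each group of 3. Among magnum libraries at 120 days, replicate 1 holds 6511037 of gene4368 and replicates 2 and 3 hold 4406 and 53990; gene8291 is listed at 0 in all 3.

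The age change itself differed between the segments for 389 genes, tested as the interaction of age and segment in the same limma fit. For 239 the change was higher in the uterus: 161 of these fell in the magnum, 121 rose in the uterus, and 43 did both. For 150 it was lower in the uterus: 117 of these rose in the magnum, 41 fell in the uterus, and 9 did both. The median log2 changes were -1.63 in the magnum and 1.16 in the uterus for the first group, and 1.63 and -0.58 for the second. Of the 239, 18 were listed at 0 in all libraries of a group, as were 5 of the 150, and the fitted interaction of such a gene depends on the pseudocount. Without them the medians were -1.64 and 1.09 for the first group and 1.62 and -0.58 for the second. For this reason no interaction is given for gene8291, listed at 0 in the magnum at 120 days. The other 3 examples did not pass: gene4368 had an interaction of -7.56 ± 2.62 (SE, adjusted p = 0.156), gene17377 of -5.73 ± 1.76 (adjusted p = 0.114) and gene11472 of -0.43 ± 0.41 (adjusted p = 0.633).

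The number of interaction genes depended on single libraries. Without magnum replicate 1, 2 or 3 at 120 days the counts were 453, 90 and 75 higher and 383, 53 and 39 lower, and without magnum replicate 2 at 300 days 102 and 62. Without uterus replicate 2 or 3 at 120 days they were 136 and 127 higher and 81 and 76 lower, and without uterus replicate 1, 2 or 3 at 300 days 77, 72 and 100 higher and 44, 46 and 59 lower. Without replicate 1 of both segments at 120 days they were 560 and 407, with library totals 8946 and 74, with same-numbered libraries of an age as blocks 432 and 296, and with the FPKM values 231 and 245, where genes whose change was higher in the uterus made up 48.5% of the calls in place of 61.4%.

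**Figure D5:**
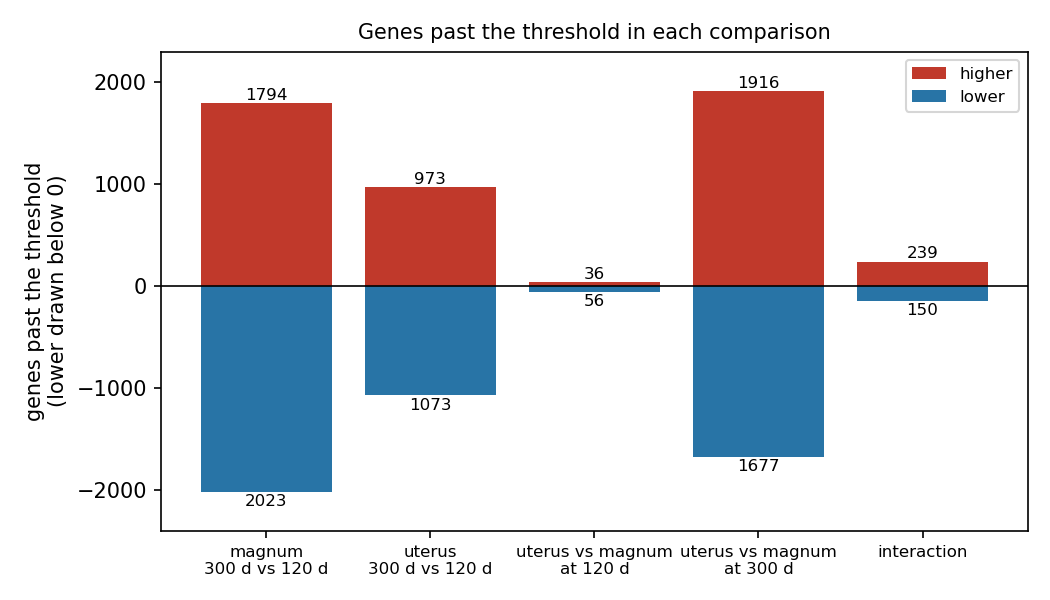
Number of genes past the adjusted p threshold in each of the 5 comparisons, drawn upward where higher and downward where lower in the first-named group; the interaction is the uterus age change minus the magnum age change. The segments differ in 36 and 56 genes at 120 days and in 1916 and 1677 at 300 days.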

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

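The tests on regrouped libraries in this part were specified after the counts of genes had been seen. The age change differed between the segments, by the interaction test, for 239 genes in the direction of the uterus and 150 in the direction of the magnum. Of the first, 115 fell in the magnum without a call in the uterus and 74 rose in the uterus without a call in the magnum. Of the second, 103 rose in the magnum without a call in the uterus. Genes listed at 0 in all libraries of a group, whose interaction depends on the pseudocount, made up 18 of the 239 and 5 of the 150. When age labels were regrouped within segments, 6 of 100 groupings, the real one included, gave at least the 389 genes of the real one. The highest of the others gave 5062 genes, from exchanging the ages in 1 segment, which by construction turns changes in the same direction in both segments into differences. The other 4 regrouped the libraries of 1 segment alone, which leaves the age change of the other segment standing as a difference. The 77 groupings that mixed the ages in both segments gave at most 2, but mixing also adds the age change to the residual spread. The share of 6 of 100 therefore cannot decide on chance, which this test does not exclude. After the additive effects of age and segment had been subtracted, 1 of 100 groupings, the real one, gave 389 genes or more and the highest other gave 63. That share does not decide on chance either. The groupings moved the libraries of each segment independently, which breaks the pairs that same-numbered libraries form at 120 days. Mixed groupings also move the interaction left in the values into the residual spread, which lowers their counts. With same-numbered libraries of an age kept together there are 10 splits, too few for a share under 0.05: the real one (1 of 10) gave 728 genes, in the fit with a block within age, and the highest other 0.

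For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each only the real split (1 of 10) gave a count as large. The other splits move the difference between the real groups into the residual spread, which lowers their counts. The contrasts below therefore do not decide on chance. The age comparison of the magnum gave 3817 genes against at most 10 in the other splits, and that of the uterus 2046 against at most 0. Between segments the counts were 92 against at most 0 at 120 days and 3593 against at most 1 at 300 days.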

How the results depend on the processing

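The pseudocount of 10 and the fits without replicate 1 of both segments at 120 days were chosen after the data were seen; the others were planned. Of 280 alternatives to the 11 called results followed for the example genes, 264 kept direction and call, 16 lost the call and 0 turned direction. The lost calls were those of gene17377 (12) and gene8291 (3) between segments at 120 days and of gene4368 in the magnum (1). Fitted sizes of gene8291 against the magnum at 120 days depend on the pseudocount. The counts were within 1.5 times under median-of-ratios and upper quartile rescaling, without the 20 most abundant genes, with both other filters on the gene table and with a pseudocount of 10. Causes were not tested unless stated.

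Dividing by library totals lowers all other genes where a few take most of a library, and shifted the median log2 change by -1.78 in the magnum age comparison, 1.84 between segments at 300 days and 1.61 in the interaction. It gave 131 higher and 12378 lower genes in the magnum, 331 higher in the uterus, 12351 higher and 246 lower between segments at 300 days, and 8946 and 74 in the interaction. Upper quartile rescaling shifted the magnum median by -0.10. With FPKM and a pseudocount of 1, the uterus against magnum counts were 19 higher and 27 lower at 120 days and 2599 lower at 300 days, the interaction had 245 lower, and 37 segment differences were shared between ages. With a pseudocount of 0.1 these were 23, 35, 2617 and, shared, 52. With no filter 32 and 2541 were lower and 41 shared. Fits of the 2 groups alone, with fewer libraries to estimate the spread, gave 1025 higher in the magnum, 2 higher and 1 lower between segments at 120 days, and 2 shared between ages. A minimum log2 change of 1 left 1013 higher in the magnum, 596 higher in the uterus and 1088 lower between segments at 300 days.

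With the replicate number as a block in all 12 libraries, 20 genes were higher in the uterus at 120 days and 51 segment differences were shared between ages. With a block within age, as the pairing at 120 days would ask, the counts at that age were 35 and 61, with 61 of the 92 genes shared, and the interaction had 432 higher and 296 lower. Between segments at 300 days, where pairing is undecided, the block within age gave 4771 calls and kept 3533 of the 3593. The replicate block moved no other count by over 1.5 times. Without replicate 1 of both segments at 120 days, 560 and 407 genes passed in the interaction, 14 and 29 between segments at 120 days, and 1501 and 1624 in the uterus, with 1723 age changes shared between segments and 39 segment differences shared between ages.

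Leaving out each library in turn gave 796 to 1983 higher and 996 to 2329 lower in the magnum, 390 to 1240 higher and 532 to 1387 lower in the uterus, 15 to 65 higher and 17 to 69 lower between segments at 120 days, 1329 to 2228 and 1133 to 1795 at 300 days, and 72 to 453 and 39 to 383 in the interaction. Shared age changes ran from 532 to 1325 and shared segment differences from 31 to 116. Where an arm kept 2 libraries, these were assumed to vary like the other groups. The planned count models, and the gene list tests with their alternatives, were not run. Depth is unknown in 8 libraries, where a listed 0 stands for a scaled value cut to 0 and does not exclude a read.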

Other observations

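All tests of explanations in this part were chosen after the patterns had been seen. Loci with a new-gene label changed with age less often than numbered genes. In the magnum 16.5% of the 1114 such loci tested passed, against 26.4% of the others (Fisher's exact test across genes, which are not independent, two-sided, p = 5.24e-14), and in the uterus 9.16% against 14.1% (p = 1.52e-06). By the same exact test between segments, the shares were 23.5% and 24.2% at 300 days (p = 0.636) and 1.08% and 0.581% at 120 days (p = 0.0688). Of those that changed in the uterus, 70 rose and 32 fell, while in the magnum 71 rose and 113 fell. Across genes, gene length had a Spearman correlation of -0.256 with the segment difference at 120 days and of -0.031 with that at 300 days.

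Variation between the 3 libraries of a group was larger at 120 than at 300 days, which in the magnum rested on replicate 1. Among genes with a highest value of at least 1000, a range of at least 4-fold within the group was found for 259 of 4914 genes in the magnum and 342 of 5054 in the uterus at 120 days, and for 69 of 5153 and 61 of 4665 at 300 days. A range of at least 100-fold was found for 23, 9, 5 and 2 genes in that order. Between pairs of libraries, over the same genes, magnum replicates 2 and 3 at 120 days differed at least 4-fold for 18 genes, fewer than the 27 to 42 of the magnum pairs at 300 days, while the pairs with replicate 1 gave 154 and 243. Leaving out uterus replicate 1, 2 or 3 at 120 days gave 164, 79 and 289 genes, and leaving out uterus replicate 1, 2 or 3 at 300 days gave 53, 50 and 3. Across genes, magnum replicates 2 and 3 at 120 days correlated at 0.966, above the magnum pairs at 300 days, and the pairs with replicate 1 at 0.900 and 0.931.

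In both segments, replicate 1 at 120 days lay part of the way toward 300 days. On a scale from the other 120-day libraries (0) to the 300-day libraries (1), over genes called without the library itself, its median position was 0.419 in the magnum and 0.472 in the uterus, where 300-day libraries lay at 0.782 to 1.01 and 0.905 to 0.966, so a 300-day library under a wrong label is argued against in both. Mixing in 300-day material would add the same fraction to every gene, but for the magnum 37.5% at most of 48 genes at least 16-fold higher at 300 days lay within 2-fold of the median fraction, which argues against it. For the uterus the share was 50% of 14 genes at most, which alone does not decide. Over the 3 possible donors, the 5th percentile of the fractions of these 14 genes was 0.0193% to 0.0275%. The 95th percentile was 58.2% to 112%. Such a spread argues against a common mixed fraction for the genes at the ends, but with 14 genes each percentile rests on few of them. Mixing is therefore not decided for the set. A candidate explanation that stays open, and was not tested, is that hens of one age differ in how far the oviduct has matured.

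Genes most abundant in the magnum at 300 days stood above 0 in every uterus library. The uterus libraries held gene4368 at 0.00791% to 0.0151% of its mean in the magnum at 300 days, and 0 of 150 values, from 25 other genes in 6 libraries, lay below 0.5 times the fraction of gene4368 in the same library. Of the 150 values 32.7% (49) lay within 2-fold of that fraction and 101 above it, which argues against carry-over of magnum reads or RNA as the whole source of these levels. Carry-over may still set the floor, and low transcription in the uterus stays open. Lower values do occur: against 1 common bar of 0.00396%, 1 of the 26 genes lay below it in each of magnum replicates 2 and 3 at 120 days, and 0 in replicate 1 and in the uterus libraries.

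Fewer genes were detected at 300 than at 120 days in both segments, without overlap between the ages. Above 0 were 15361 ± 208 against 16134 ± 76.8 in the magnum and 15963 ± 32.3 against 16241 ± 5.13 in the uterus (SD, n = 3 each), and with a minimum of 50 scaled counts the gaps were 605 and 288 genes. In the magnum the very abundant genes leave fewer reads for the others, but the gap at 50 argues against this as the whole cause, and in the uterus no few genes dominate. To close the magnum gap at 50, values at 300 days would have to rise by 0.60 on the log2 scale, against 0.12 in the FPKM values. The FPKM values also stand relative to a typical gene, so this contrast cannot decide on the authors' scaling as a cause. The scaling was not tested in the uterus. A difference with age in the number of genes transcribed at a measurable level may be a hypothesis for independent samples.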
